A study of Mus musculus with 7 samples.

How the data were processed

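Total RNA was extracted with Trizol from sorted cells, labelled with biotin and hybridised to 1-colour Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols and the series' design text. The deposited values are MAS5 signal, a probe set intensity on a linear scale, per the submitters' processing notes; the software version is not given in the sources used here. The authors' scaling can be read from the values: the mean intensity without the lowest and highest 2% was 500 on every one of the 7 deposited arrays, and no other between-array normalization was apparent. MAS5 subtracts mismatch signal, which makes ratios between dim values noisy and large. Present and absent calls and scanner files were not used here, so that array medians ranging from 64.4 to 94.5 served as the level below which a signal is treated as dim.

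Each sample was placed in its group by the title in the labels, which also gives the replicate number. Of 45101 probe sets, 64 controls were left out. Probe sets were named through the platform annotation, with symbols updated by Entrez ID through a RefSeq table of the GRCm38.p6 assembly, used for names alone. The annotation gave 1 gene for 34958 probe sets (34754 matched by Entrez ID), several for 932 and none for 9160. No genome build is named for these arrays, and no coordinates are reported. Log2 of the deposited intensity was taken without a pseudocount. A probe set was kept if its value was at or above the array median in at least 3 arrays without regard to group, which left 23585, of which 20162 had 1 gene; the brightest probe set stood for its gene, giving 11089 genes. Of the 83 genes called, 43 had more than 1 kept probe set, and in 2 of these another probe set had the opposite sign.

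The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, statmod 1.5.0 for the random block), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All 7 arrays entered the fit, without covariates. Where a called gene lay below the array median on every array of a group, its fold is given as a bound: the brighter group's mean against the mean, per array, of the array median. The 26 gene lists were written before the data were examined, as were the groups, the tests, the alternatives not named as later and the rule for named genes. Lists with at least 5 measured members were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 25 lists; the list of red blood cell genes had 2 measured members (median log2 change -0.30) and was not tested. The lists overlap: Atoh1, Prom1, Notch1, Hes1, Notch3 and others stand in more than 1. No list should be read as exclusive to a cell type. Of the 29 measured markers of microglia, pericytes and meningeal fibroblasts, 2 stand in another list too. On all Nestin-positive arrays 3 of the 29 lay at or above the array median, and which cells gave this signal was not tested. Named genes are Nes, Gli1, Ptch1, Gli3 and Atoh1, the 10 largest fitted rises and 10 largest fitted falls among called genes whose groups do not overlap, and up to 4 members by smallest p-value of each list with a called member or past its test. Other list members named beside the blocked counts were chosen after their values were seen.

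Replicate numbers 1, 4 and 5 occur in both groups, and replicate 3 in the Nestin-positive group alone. Over the genes tested, deviations from the group means of same-numbered samples correlated with r = 0.71, 0.39 and 0.47 for replicates 1, 4 and 5, across genes, which are not independent replicates; pairs with different numbers lay between -0.60 and 0.19. The numbers were therefore taken to pair the samples, from the data and not from a statement in the labels. The rule (r over 0.1) was set before the fits were run, and the correlations and the calls of both fits came out of the same run. Nestin-positive replicates 4 and 3 also passed 0.1 with Nestin-negative replicate 5 (0.19 and 0.14). Deviations cancel within a group, so a high r in a pair lowers that of others. The pairing is thus an assumption that these correlations do not establish. A fit with the replicate number as a fixed block rests on these 3 pairs, with 2 residual degrees of freedom per gene before moderation and 19.8 after it. Its standard errors and p-values therefore rest mostly on spread pooled over genes, and less on each gene's own spread over the pairs. Values of this fit are given beside a result where they change the call or move a count by over 1.5 times.

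RNA quality was read from control probe sets. The 3' to 5' signal ratio of the beta-actin control lay between 1.68 and 1.99 (exact permutation test, p = 0.514), lower in the Nestin-positive sample of all 3 pairs, and that of Gapdh between 1.09 and 1.38 (exact permutation test, p = 0.943), higher in 1 of the 3 pairs. The hybridisation spike BioB was lower on Nestin-positive arrays (99.1 against 132, exact permutation test, p = 0.0286, the smallest possible). BioB, the hybridisation spike Cre (exact permutation test, p = 0.171), the poly-A spike Dap (p = 0.371) and the array median (p = 0.829) were lower in the Nestin-positive sample of all 3 pairs. These permutation tests take no account of the pairs. Arrays correlated with r from 0.93 to 0.98, and 41.9% and 29.0% of the variance lay on the first and second principal components. No arrays held identical values.

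The scripts were tested on data simulated from these arrays in 5 runs, with 200 of 11089 genes changed and the G2 and mitosis list shifted beside them. With samples simulated as not paired and no block, 15.1% of genes changed by 0.5 log2 units, 66.2% of those changed by 1 and 92.3% of those changed by 2 were recovered, with 4.95% of calls false; the block on these recovered 0%, 19.8% and 75.4% with 2.79% false. With samples simulated as paired, the block recovered 4.09%, 57.0% and 91.9% with 4.91% of calls false, and the fit without it 12.6%, 59.4% and 92.8% with 0.90% false. Camera without the block called a list shifted by a known amount in 5 of 5 runs, and made 2 calls of lists that were not shifted with samples simulated as paired and 0 with samples simulated as not paired. Genes were simulated independently of each other, so these runs do not test list calls where genes are correlated. Alternatives covered quantile normalization and median centring, the filter, a pseudocount, a floor, the summary of probe sets, the variance model, the block, each array left out, the list test and the threshold.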

Results

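Gene expression was measured in granule neuron precursors, the dividing cells that give rise to the granule neurons of the cerebellum, taken from mice in which Math1-Cre removes Ptch1, the inhibitory receptor of the Hedgehog pathway, from this lineage. A Nestin-CFP reporter, a fluorescent protein driven by regulatory sequence of the Nestin gene, was used to sort the cells by flow cytometry into a Nestin-positive and a Nestin-negative fraction. RNA was extracted without culture and hybridised to 1 array per sample, giving 4 Nestin-positive arrays (replicates 1, 3, 4 and 5) and 3 Nestin-negative arrays (replicates 1, 4 and 5). The sample labels give postnatal day 7 and name the tissue medulloblastoma, whereas the description of the series gives postnatal day 4, and the values here hold for whichever age applies. The number of arrays limits the precision of every value. The labels do not say that the samples came from separate animals. The p-values thus measure the spread between these samples, in part pooled over genes by the moderation, and some of that spread may be technical.

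Nes itself, which encodes the intermediate filament protein Nestin, was higher in the Nestin-positive fraction by 1.73 ± 0.21 (SE) on the log2 scale, or 3.32-fold (limma, adjusted p = 0.0282, n = 4 and 3). The brightest Nes probe set had a signal of 643 ± 161 (SD, n = 4) in Nestin-positive and 190 ± 23.5 (SD, n = 3) in Nestin-negative cells. Of 2 dimmer probe sets, the one with 7.30-fold higher signal lay below the array median on Nestin-negative replicate 1. The one with 6.53-fold lay below it on all 3 Nestin-negative arrays and on Nestin-positive replicate 1. The size of these folds is therefore uncertain. An exact two-sided permutation test over the 35 splits of the arrays gave p = 0.0286, the smallest value this design allows. Since Nestin defined the sort, this value checks the labels and is no finding between the fractions. The adjusted p of Nes was 0.0635 without Nestin-positive replicate 5, 0.0563 without Nestin-negative replicate 1, 0.119 without Nestin-negative replicate 4 and 0.0587 without Nestin-negative replicate 5, and 1.0e-06 with the replicate number as a block.

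The comparison the design implies asks how Ptch1-deficient precursors that express Nestin differ from those that do not. Of 11089 genes tested, 19 were higher and 64 lower in Nestin-positive cells at the adjusted threshold of 0.05. The genes that rose included transcriptional regulators, a Notch ligand and Hedgehog-responsive genes, and those that fell included an axonal adhesion molecule, potassium channels and myeloid genes. All 83 had non-overlapping values in the 4 and 3 arrays, which entails the same direction in all 3 pairs of same-numbered samples. Selection by small p-values favours such genes, so neither adds support to the calls. Over all genes, 15.0% had non-overlapping groups, where chance gives 5.71%. The replicate number was taken as a pairing from these data, not from the labels. With it as a block, 1106 genes passed, 397 higher and 709 lower, and these included all 83. The count without the block was fragile. It was 10 without Nestin-positive replicate 1, 40 without Nestin-positive replicate 3, 5 without Nestin-negative replicate 1 and 1 without Nestin-negative replicate 5. Limma called 0 genes without Nestin-positive replicate 5 (1311 at an unadjusted p under 0.05) and 0 without Nestin-negative replicate 4 (1131 unadjusted). Quantile normalization gave 22 genes, 9 higher and 13 lower. The blocked count was 695 without the pair of replicate 1.

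Crym, which encodes a thyroid hormone-binding protein of the cytosol, lay below the array median on all 3 Nestin-negative arrays and rose at least 3.86-fold (adjusted p = 0.0328). Pdlim3, a PDZ and LIM domain protein of the actin cytoskeleton, rose by 2.31 ± 0.31 (SE) on the log2 scale, or 4.96-fold (adjusted p = 0.0282). The LIM-only transcriptional cofactors Lmo1 and Lmo3 rose 3.51-fold and 2.39-fold. Sox1, a transcription factor of neural progenitors, rose 2.76-fold (log2 change 1.47 ± 0.21 SE), and Jag1, a Notch ligand, rose 2.63-fold (log2 change 1.40 ± 0.18 SE). Nmrk1, a nicotinamide riboside kinase, rose 2.85-fold, the AMPA receptor auxiliary subunit gene Cacng5 rose 2.26-fold, and the uncharacterised 2700046A07Rik rose 2.44-fold. Adjusted p-values of these genes lay between 0.0282 and 0.0470.

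**Figure D1:**
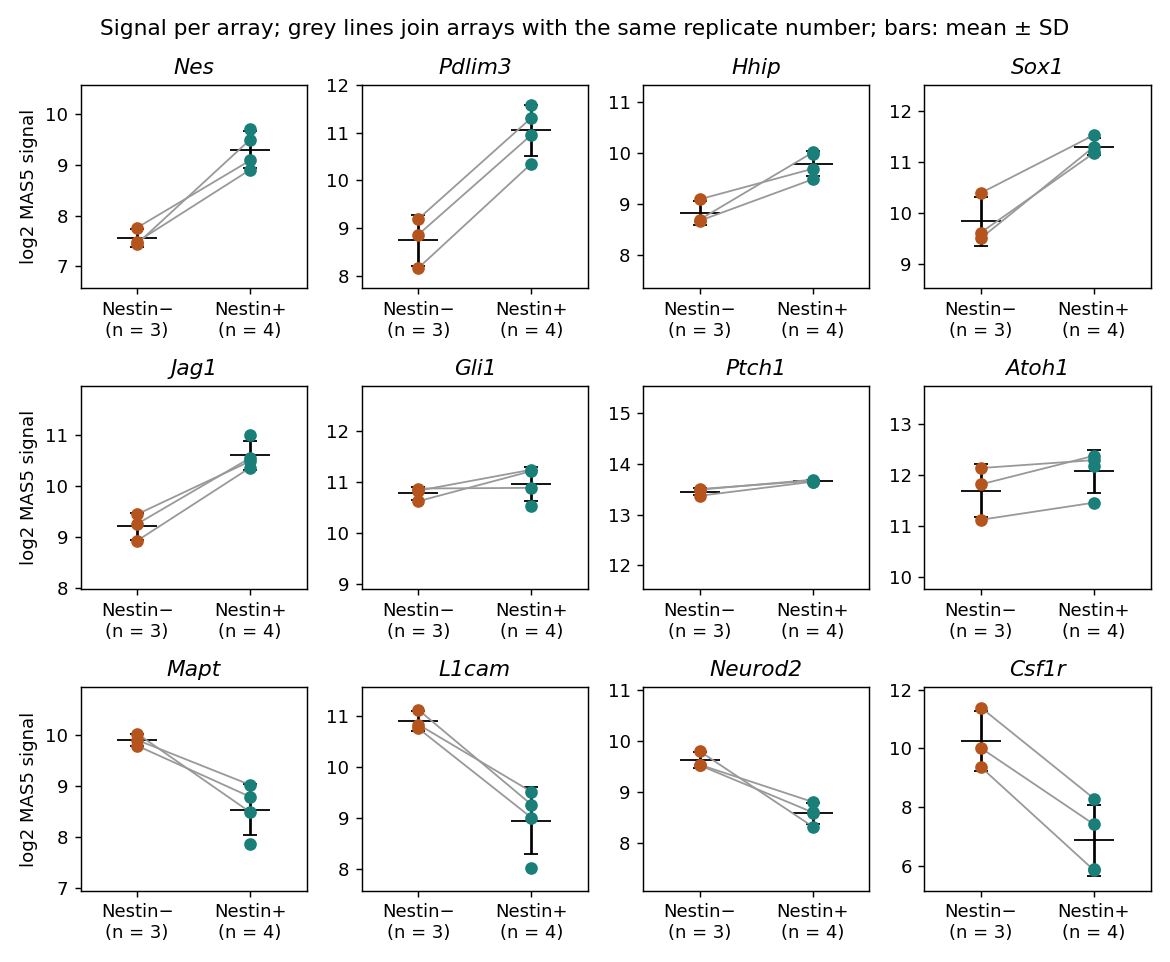
Log2 MAS5 signal of 12 genes on each array (vertical axis, one point per array) in Nestin-negative (n = 3) and Nestin-positive (n = 4) cells; black bars are the mean ± SD, and grey lines join arrays that share a replicate number. Pdlim3 averaged 8.74 in Nestin-negative and 11.05 in Nestin-positive cells, Csf1r averaged 10.26 and 6.87, and Ptch1 averaged 13.45 and 13.66.

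Among the genes that fell, Csf1r, the CSF1 receptor of microglia and macrophages, was lower in Nestin-positive cells (log2 change -3.39 ± 0.63 SE, adjusted p = 0.0480). Its signal lay below the array median on Nestin-positive replicates 1 and 3, and with these raised to it the fall was 8.53-fold. The log2 change was -2.30 with the mean of its probe sets, and its adjusted p was 0.0586 to 0.161 with each array left out. Lyz2, a lysozyme of myeloid cells, was at least 3.78-fold lower, Tunar at least 2.17-fold lower and the cation channel gene Trpv2 at least 1.82-fold lower, as their signals were below the array median on every Nestin-positive array. The transcriptional corepressor gene Skor1 was 4.51-fold lower and the hyaluronan-binding protein gene Cemip 4.40-fold lower. L1cam, an adhesion molecule of growing axons, was 3.89-fold lower (log2 change -1.96 ± 0.30 SE, adjusted p = 0.0328). Kcna1, a voltage-gated potassium channel gene, was 3.23-fold lower, the chemokine gene Cxcl12 3.35-fold lower and the zinc finger gene Zmat4 3.42-fold lower. Adjusted p-values of these genes lay between 0.0317 and 0.0480.

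Hedgehog target genes as a list shifted upward in Nestin-positive cells. The 14 measured members had a median log2 change of 0.24 (camera, adjusted p = 0.0014; adjusted p = 0.274 with an estimated correlation). Pdlim3 and Hhip, a Hedgehog-binding antagonist induced by the pathway, rose, the latter by 0.97 ± 0.17 (SE) on the log2 scale (adjusted p = 0.0403). Adjusted over the list alone, 3 members were higher and 1 lower. With the replicate block, 7 of the 14 rose, among them Prom1 (log2 change 0.56 ± 0.10 SE), Ccnd1 (0.34 ± 0.10) and Atoh1 (0.35 ± 0.10, adjusted p = 0.0366), and 1 fell, the growth factor gene Igf2 (-1.74 ± 0.14). Without the replicate block, none of the following passed. Gli1, the transcriptional effector most often used as a readout of the pathway, differed by 0.19 ± 0.18 (adjusted p = 0.682; 0.34 ± 0.12 and 0.0711 with the block). Ptch1, the gene that Math1-Cre removes from this lineage, differed by 0.21 ± 0.09 (limma, adjusted p = 0.327, and 0.201 with the block). Whether its probe set lies in the deleted part is not given in the sources used here. Atoh1, the transcription factor that defines the lineage, differed by 0.39 ± 0.27 (adjusted p = 0.576). Leaving out Pdlim3 and Hhip, an alternative chosen after seeing the data, gave a median of 0.20 (adjusted p = 0.0762; 0.0144 with the block). The 18 measured components of the Hedgehog pathway had a median of 0.05 (0.00 to 0.11 with each array left out; adjusted p = 0.105; 0.0389 without Nestin-negative replicate 1), and Gli3, a mostly repressive Gli factor, differed by 0.67 ± 0.18 (adjusted p = 0.122; 0.0108 with the block).

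Genes of cell division shifted upward together. All 35 measured G2 and mitosis genes had positive log2 changes, with a median of 0.40 (camera, adjusted p = 7.7e-21; adjusted p = 0.244 with an estimated correlation), and 33 were higher in all 3 pairs. Limma called 0 over all genes (26 at an unadjusted p under 0.05), 25 were higher adjusted over the list alone, and 28 rose with the replicate block. Examples with the block are Top2a, a topoisomerase of dividing cells (0.49 ± 0.10 SE, adjusted p = 0.0024), the centromere protein gene Cenpf (0.65 ± 0.12, 0.0013) and the spindle checkpoint kinase gene Bub1b (0.45 ± 0.10, 0.0075). The 32 S phase and replication genes had a median of 0.22 (adjusted p = 1.6e-06; adjusted p = 0.422 with an estimated correlation; median 0.11 without Nestin-negative replicate 1), with 0 called by limma, also adjusted over the list alone (8 at an unadjusted p under 0.05), and 5 higher with the block, Pola1 and Mcm10 among them. The 30 DNA repair genes had a median of 0.34 (adjusted p = 5.4e-11; adjusted p = 0.0773 with an estimated correlation). Limma called 0 of them over all genes (16 at an unadjusted p under 0.05), 4 were higher adjusted over the list alone, and 9 rose with the block, including Brca2 (0.52 ± 0.12), Xrcc6 (0.45 ± 0.12) and Rad50 (0.49 ± 0.13). The 15 cell cycle inhibitors had a median of -0.06 with a camera statistic of the other sign (adjusted p = 0.917; -0.09 to 0.00 with each array left out), and the 15 p53 target genes a median of -0.02, again with the statistic of the other sign (adjusted p = 0.843; -0.07 to 0.05).

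Granule neuron differentiation genes shifted the other way. All 27 measured members had negative log2 changes, with a median of -0.58 (camera, adjusted p = 1.8e-16; adjusted p = 0.0859 with an estimated correlation). The 4 members that fell were L1cam, the A-type potassium channel gene Kcnd2 (log2 change -1.45 ± 0.20 SE), the microtubule-binding protein gene Mapt (-1.37 ± 0.25) and the transcription factor gene Neurod2 (-1.04 ± 0.15). Adjusted over the list alone 21 were lower, and with the replicate block 19 fell. In contrast, the 16 measured granule neuron precursor genes had a median of 0.03 (camera, adjusted p = 0.843), and of -0.10 to 0.14 with each array left out. With the block 3 were higher and 1, Zic4, was lower. The neural stem and progenitor list had a median of 0.22 over 23 genes (camera, adjusted p = 0.00099, and 0.43 with an estimated correlation). Nes and Sox1 were called, and 6 members were higher adjusted over the list alone. Nes, which defined the sort, counts among these, and the list was not tested without it. The list median was 0.34 without Nestin-positive replicate 1, 0.09 without Nestin-positive replicate 3 and 0.12 without Nestin-negative replicate 1. Nestin-positive replicate 3, which has no partner, had the highest signal of all arrays for 11 of the 23 genes, Fabp7, Slc1a3, Tnc and Ednrb among them. Its astrocyte list median was 0.71 relative to the mean of all arrays, against -0.86 to 0.02 on the other Nestin-positive arrays and -0.88, 0.76 and 0.74 on Nestin-negative replicates 1, 4 and 5. The list lost its call with the block (median 0.09, adjusted p = 0.112), where 7 members rose, including Hes1 (0.93 ± 0.14), Notch1 (0.80 ± 0.13) and Vim (0.66 ± 0.10), and 6 fell. In the Notch pathway list, with 18 members and a median of 0.10 (adjusted p = 0.0243; adjusted p = 0.43 with an estimated correlation; 0.151 without Nestin-negative replicate 1, with a median of 0.05; medians 0.21 and 0.04 without Nestin-positive replicates 1 and 3), Jag1 rose, 3 members were higher adjusted over the list alone, and with the block 3 rose and Notch3 fell. Notch2 differed by 0.39 ± 0.15 (adjusted p = 0.284).

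Marker lists of microglia, pericytes and meningeal fibroblasts were lower in Nestin-positive cells, but the arrays of the fractions overlapped for the pericyte and meningeal lists. Relative to all arrays, the pericyte list mean was -0.54 on Nestin-negative replicate 1, and -0.03 and 0.23 on Nestin-positive replicates 4 and 5. The meningeal list mean was -0.56 on Nestin-negative replicate 1, and 0.12 and -0.03 on Nestin-positive replicates 4 and 5. All 11 measured microglia and macrophage markers had negative log2 changes in all 3 pairs, with a median of -2.67 (camera, adjusted p = 1.3e-11; adjusted p = 0.274 with an estimated correlation). Csf1r and Lyz2 fell, and all 11 were lower adjusted over the list alone and with the replicate block, for example the cathepsin gene Ctss (-2.79 ± 0.23 with the block; -2.21 with values under the array median raised to it). The 11 pericyte and smooth muscle markers had a median of -1.78 (adjusted p = 1.3e-05; adjusted p = 0.43 with an estimated correlation), with 0 called by limma (8 at an unadjusted p under 0.05), 5 adjusted over the list alone and 10 with the block, including Acta2 (-2.09 ± 0.20; -1.84 with values raised) and Vtn (-2.37 ± 0.19; -1.88 with values raised). The 7 meningeal fibroblast markers had a median of -1.55 (adjusted p = 0.0043; adjusted p = 0.43 with an estimated correlation), with 0 called by limma (5 at an unadjusted p under 0.05), 5 adjusted over the list alone and 5 with the block, including the collagen genes Col1a2 (-1.55 ± 0.19) and Col3a1 (-1.15 ± 0.18). Astrocyte and Bergmann glia markers (22 genes, median -0.25, adjusted p = 0.917) had medians of 0.07 and -0.53 without Nestin-positive replicates 1 and 3. The medians were -0.84 (adjusted p = 0.0034), 0.03 and -0.01 without Nestin-negative replicates 1, 4 and 5. They passed with the block (median -0.53, adjusted p = 3.2e-05; adjusted p = 0.359 with an estimated correlation; medians -0.91, -0.42 and -0.49 without pairs 1, 4 and 5), with 9 lower, including Aqp4 (-1.69 ± 0.14), and 2 higher, Slc1a2 and Gdf10. The 5 measured GABAergic interneuron markers (median -0.37, adjusted p = 0.129; 0.0146 without Nestin-positive replicate 1; median -0.76 without Nestin-positive replicate 3) passed with the block too (median -0.76, adjusted p = 0.0167; adjusted p = 0.471 with an estimated correlation). There, Tfap2b, below the array median on Nestin-positive replicates 1, 4 and 5, was lower by at least 1.15 on the log2 scale and Gad1, below the array median on all Nestin-positive arrays, was at least 4.66-fold lower, while Pvalb rose by 0.47 ± 0.15. Endothelial markers had a median of -0.37 over 16 genes (adjusted p = 0.272), which was -0.06 without Nestin-positive replicate 1 and -0.73 (adjusted p = 0.0012), -0.13 and -0.06 without Nestin-negative replicates 1, 4 and 5. Of 99 genes in the lists of other cell types, 2 were among the 64 lower and 0 among the 19 higher genes; with the block, 44 were lower and 8 higher.

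**Figure D2:**
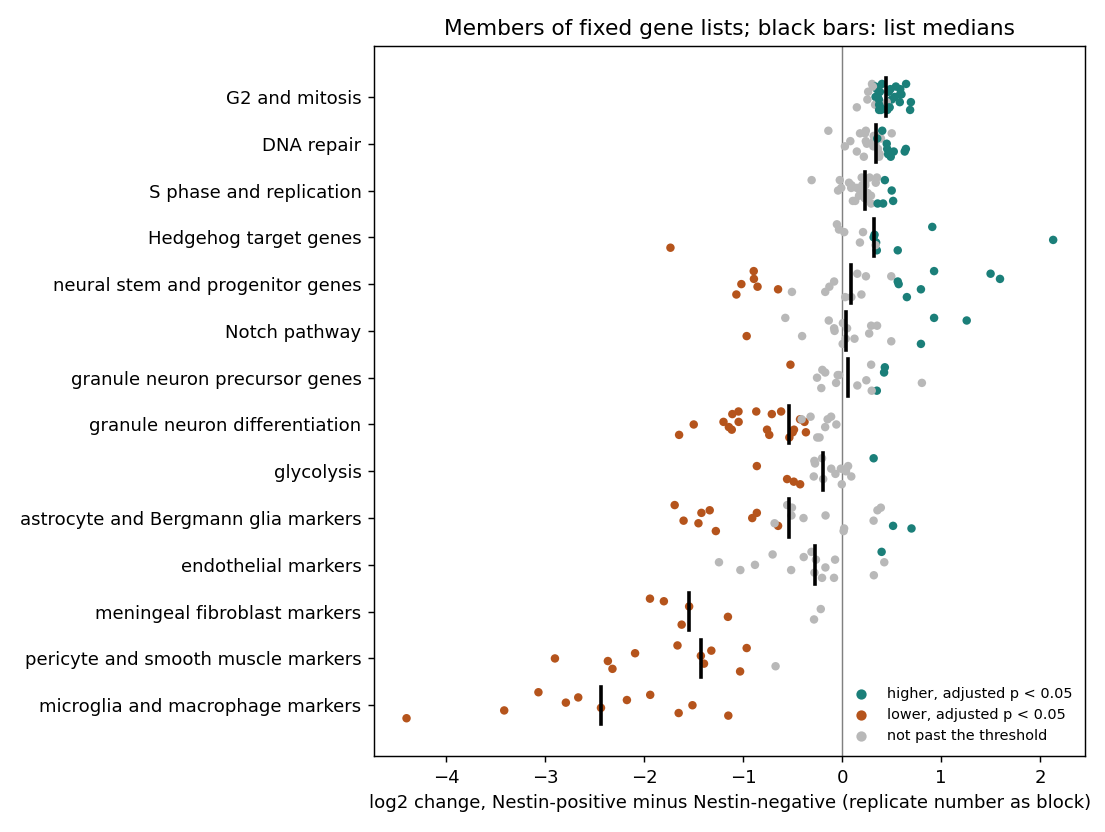
Log2 change of each measured member of 14 gene lists (horizontal axis, Nestin-positive minus Nestin-negative, replicate number as a block; one point per gene), coloured by direction where the adjusted p was under 0.05 and grey otherwise; black bars are list medians. The medians run from -2.44 for microglia and macrophage markers to 0.45 for G2 and mitosis genes, and that of granule neuron precursor genes is 0.06.

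Glycolysis genes had a median of -0.21 over 17 genes (camera, adjusted p = 0.0398; adjusted p = 0.43 with an estimated correlation). Limma called 0 members over all genes (3 at an unadjusted p under 0.05), 2 were lower adjusted over the list alone, and with the block 4 fell, Tpi1, Pfkm, Aldoa and Aldoc, and Hk2 rose. The list's adjusted p was 0.0714 without Nestin-positive replicate 3 and 0.185 without Nestin-negative replicate 5, and with the block 0.110 without pair 5. Extracellular matrix and basement membrane genes had a median of -0.54 over 24 genes (adjusted p = 0.264). The median was -0.24 and -0.31 without Nestin-positive replicates 1 and 4. It was -1.07 (adjusted p = 3.5e-05), -0.11 and -0.06 without Nestin-negative replicates 1, 4 and 5. With the block the list passed (adjusted p = 0.0185; adjusted p = 0.669 with an estimated correlation), though not without pair 4 (median -0.14, adjusted p = 0.571) or pair 5 (0.03, 0.657), with 8 members lower, Lamb1 and Sparc among them, and 4 higher. Among the 10 intermediate filament and lamin genes (median -0.15, adjusted p = 0.917; -0.24 to 0.05 with each array left out) Nes rose, and with the block Vim rose while the neuronal filament genes Ina (-0.64 ± 0.11) and Nefl (-0.89 ± 0.13) fell. Immediate early and dissociation stress genes had a median of -0.27 over 22 genes (adjusted p = 0.194; 0.0095 without Nestin-positive replicate 1 and 0.0474 without Nestin-negative replicate 5), which was -0.06 with the block (adjusted p = 0.853), without Nestin-positive replicate 3 (0.834) and without Nestin-negative replicate 1 (0.695). The lists of oligodendrocyte lineage markers, Purkinje cell markers, unipolar brush cell and rhombic lip markers, and Wnt and BMP response genes did not pass with camera. Their medians were -0.26 (14 genes, adjusted p = 0.216), -0.12 (6 genes, 0.917), -0.61 (5 genes, 0.264) and -0.20 (11 genes, 0.516). With each array left out these ran from -0.31 to -0.10, -0.28 to 0.05, -0.64 to -0.45 and -0.22 to -0.10. The Purkinje list had its lowest median without Nestin-negative replicate 1 and its highest without Nestin-positive replicate 1. Fry called the unipolar brush cell list (adjusted p = 0.0388). In all, 11 of 25 lists passed, 6 higher and 5 lower, and with the block 13, 5 higher and 8 lower. With an estimated correlation camera called 0 of 25, with or without the block (4 lists at an unadjusted p under 0.05 in each), while fry called 4, of which 3 are among the 11.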

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

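The tests on cell types, array scaling, dim probe sets, dilution and postmitotic neurons below were chosen after the results were seen; those on other splits of the arrays were set before they were run.

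In the 4 Nestin-positive samples, 2 of 79 measures tested held a sample far from the others, where chance flags about 1 in 20. Trpv2 had a log2 signal of 4.54 in replicate 3 against 5.39 to 5.53 in the other samples. Kcnd2 had a log2 signal of 8.0 in replicate 1 against 8.65 to 8.73 in the other samples. Of 3423 kept probe sets without a single gene name, which enter no comparison of genes, 0 passed the threshold with limma and 96 did with the replicate block, 26 higher and 70 lower.

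Of the 35 splits of the 7 arrays into groups of 4 and 3, 2 called as many genes as the real one or more, the real one counted. Chance thus cannot be excluded for the 83 genes by this count. The highest other split called 140 genes. It sets Nestin-positive replicates 1 and 3 and Nestin-negative replicate 1 against the rest, keeps all 3 pairs together, and points to a structure of the samples apart from the sort. Among the 8 splits that part all 3 pairs, the highest other called 0 genes by limma. As many lists as the real 11 passed in 4 of the 35 splits, the real one counted (highest other 11). A Hedgehog target statistic as large arose in 3 of the 35, again with the real one counted. The highest other -log10 p of camera was 5.11 against the real 3.35, so that chance is not excluded for these either. The split with 5.11 sets Nestin-positive replicates 1, 4 and 5 against the rest, and differs from the real one by Nestin-positive replicate 3 alone. With the replicate block there are 4 splits that part every pair, too few for a share under 0.05; the real one called 1106 genes (1 of 4 splits with as many) and the highest other 0.

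Markers of microglia, pericytes and meningeal fibroblasts were lower in Nestin-positive cells, though the arrays of the fractions overlapped for the pericyte and meningeal lists. The median log2 change of the 29 markers with the block was -1.66 and stayed at -1.54 after quantile normalization (SD over 3 pairs 0.24). This argues against unlike signal distributions between arrays as the cause. Quantile normalization cannot show a shift common to all genes, and no fit was rescaled to the spikes. Noise of dim probe sets stays open: with values under the array median raised to it, which moved 65 of 203 values, the median was -1.43 (SD over 3 pairs 0.84), with -0.40 in pair 1, -1.57 in pair 4 and -2.03 in pair 5. Against it as the whole cause, 23 of the 29 markers stayed lower by over 1 log2 unit in the mean of the pairs, though pair 1 keeps it open. On all Nestin-negative arrays 21 of the markers lay at or above the array median. The filter, which asks for this on at least 3 arrays, favours such markers, so that count does not bear on noise. A candidate explanation is that the reporter-negative gate held other cell types, which a sort on Nestin-CFP alone would not remove. It was not decided: 93.1% of the 29 markers were lower in all 3 pairs, which restates the pattern, and expression by the precursors themselves predicts the same. Mean log2 signals of Col3a1, Rgs5 and Csf1r in Nestin-negative cells were 11.39, 10.80 and 10.26, and no share of other cells was estimated.

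Mitosis genes were higher and neuronal genes lower in Nestin-positive cells. Dilution of granule-lineage RNA by other cell types would raise precursor genes alike. The mitosis median exceeded the precursor median by 0.42 ± 0.12 (SD over 3 pairs) on the log2 scale, with 0.28 in pair 4. The spread between the precursor genes was 0.37, which describes the genes and is no error of this difference. In pairs 1, 4 and 5 the mitosis medians were 0.60, 0.34 and 0.32, and the precursor medians 0.08, 0.05 and -0.14. The median precursor gene thus did not rise as the mitosis genes did. Dilution is not excluded, since the precursor genes are a mixed baseline. Their log2 changes ran from -0.49 to 0.85 without the block, and Atoh1 rose by 0.35 with it. Quantile normalization left the mitosis median with the block at 0.43 (0.45 before), which argues against unlike signal distributions between arrays as the cause. It cannot show a shift common to all genes: the median change of all genes with the block was -0.01 before and after. The BioB spike was lower on Nestin-positive arrays (99.1 against 132), and no fit was rescaled to the spikes. Such a shift alone would not move mitosis and neuronal genes apart. Both medians moved apart in 3 of 3 pairs, as they would if the reporter-negative fraction held more postmitotic granule neurons and also if each cell expressed fewer neuronal and more mitosis genes; these cannot be told apart in sorted bulk RNA. A difference between Nestin-positive and Nestin-negative precursors themselves remains a hypothesis.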

How the results depend on the processing

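Alternatives that leave out both replicate 1 arrays, one pair, or Pdlim3 and Hhip, or that combine the replicate block with another choice, were chosen after seeing the data. No named gene and none of the 11 lists called without the block changed sign among the alternatives run. Of the lists not called, 7 had a median of the other sign in at least 1 alternative: that of astrocyte markers was 0.07 without Nestin-positive replicate 1 and 0.03 without Nestin-negative replicate 4. Among the 83 genes Phf20l1 (-0.76) changed sign without Nestin-positive replicate 4 (0.21) or 5 (0.06) or Nestin-negative replicate 1 (0.20), where another probe set stood for it. The median change of all genes moved by under 0.1 with each scaling. The count of 83 genes was the least stable result: 22 with quantile normalization (9 higher), 52 without a filter, 43 with the mean of a gene's probe sets, 1828 with array weights, 53 at 2-fold or more and 261 at an adjusted p under 0.1. Limma called 0 genes without the intensity trend (1573 at an unadjusted p under 0.05) and 0 of 23585 probe sets in place of genes (2283 unadjusted), against 11089 genes. With each array left out in turn it ran from 0 to 93: 10 without Nestin-positive replicate 1, 40 without replicate 3, 93 without replicate 4 and 0 without replicate 5 (1311 unadjusted), and 5, 0 (1131 unadjusted) and 1 without Nestin-negative replicates 1, 4 and 5. It was 12 without both replicate 1 arrays.

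With the replicate block, 1106 genes passed with a fixed and 854 with a random block, 799 with quantile normalization, 706 without a filter, and 695, 1446 and 869 with the pair of replicates 1, 4 or 5 left out. The block ended the call of the neural stem and progenitor list and added 3 lists, with no other list call changed. Of 62 named genes it added 33 to the 24 called and ended 0 calls. Nes kept its direction throughout, at an adjusted p of 0.0547 without the trend (log2 change 1.73) and with log2 changes of 1.60 to 1.86 and adjusted p-values of 0.0162 to 0.119 with each array left out; the calls lost were those without Nestin-positive replicate 5 (1.80) and Nestin-negative replicates 1 (1.69), 4 (1.67) and 5 (1.83). The Hedgehog target list kept a median of 0.24 but not its call with an estimated correlation (adjusted p = 0.274) or fry (0.0762), nor with the block and an estimated correlation (median 0.32, 0.283), nor without Pdlim3 and Hhip (0.20, 0.0762); its median lay between 0.17 and 0.32 with each array left out, past the threshold in all 7. The number of lists fell from 11 to 0 with an estimated correlation, with the block (0) as without; fry called 4, of which 3 are among the 11. It lay between 10 and 14 with each array left out. The cause was not tested for any of these. With the stricter filter the pericyte, meningeal fibroblast and microglia lists, among others, and with any 1 Nestin-negative array left out the GABAergic list, had under 5 measured members and no test. Lyz2, Tunar and Trpv2 had no value in these settings. Low signal limits Crym, Lyz2, Tunar, Trpv2, Tfap2b and Gad1 to bounds.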

Other observations

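Gene families picked by their symbols were tested with camera after the data were seen. Of 24 families 8 passed without the replicate block and 5 with it, 4 of them in both. With an estimated correlation camera called 0 of 24 after adjustment, with or without the block (1 with and 4 without at an unadjusted p under 0.05), so that no family call holds under both tests. Semaphorins and plexins, synaptotagmins and complexins, zinc finger proteins and intraflagellar transport genes passed without the block alone, and glutamate and GABA receptors with it alone (adjusted p = 0.0065; 0.0855 without). The counts and changes below are with the block. Of 34 potassium channel genes 10 fell and 0 rose (median log2 change -0.40, adjusted p = 7.3e-06; adjusted p = 0.431 with an estimated correlation), among them Kcnk2 (-1.05 ± 0.15 SE), Kcna2 (-1.49 ± 0.33) and Kcnd3 (-0.71 ± 0.13). Of 22 genes with sodium and calcium channel symbols 4 fell and 1 rose (camera, adjusted p = 0.0109). The 1 that rose was Cacng5, the AMPA receptor auxiliary subunit gene, so that symbols also gather genes of other function. Of 19 genes with glutamate or GABA receptor symbols 7 fell, including Grik3 (-1.15 ± 0.21) and the metabotropic receptor gene Grm3 (-1.36 ± 0.21), while Gria2 (0.38 ± 0.12) and Gria3 (0.73 ± 0.15) rose. Of 28 kinesin genes (adjusted p = 0.0174) 8 rose, among them the mitotic Kif11 and Kif23, which also stand in the G2 and mitosis list, and Kif21a (0.73 ± 0.11), and 3 fell, the neuronal Kif5a (-0.67 ± 0.11), Kif3c and Kif21b (-0.74 ± 0.13). Of 11 cathepsin genes (adjusted p = 0.00037) 3 fell and 1 rose, and Ctss, which fell by 2.79, stands in the microglia and macrophage list. Tubulins did not pass (adjusted p = 0.0870), although 4 of 15 fell, Tubb3 and Tubb2a among them. In each of the families with values given here the median kept its sign under quantile normalization and median centring.

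Other single genes moved apart within families. Epha3 rose by 1.06 ± 0.11 with the block and Epha5 by 0.95 ± 0.23, while Ephb1 fell by 1.56 ± 0.17. Itga9 rose by 1.09 ± 0.15, and Itga8 and Itgb5 fell. The chemokine receptor gene Cxcr4 rose by 0.58 ± 0.10, and the gene of its ligand, Cxcl12, fell by 1.57 ± 0.11. These genes were chosen after their values were seen. Whether their changes lie within the precursors or in other cell types of the Nestin-negative fraction was not tested.

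A hypothesis drawn from Kcna1 and Kcnd2 was that potassium channel genes fall as a family. Without the 3 members called without the block and without Kcnd2 and Kcnj8, which stand in the neuronal and pericyte lists, 30 members were left. With the block 6 of them fell and 0 rose, with a median of -0.35 (adjusted p = 0.0033; adjusted p = 0.431 with an estimated correlation). The data do not decide it, since the call depends on the correlation assumed between genes.

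Immediate early and dissociation stress genes were lowest on Nestin-positive replicate 3, although the outlier test among the Nestin-positive samples did not flag their list mean. Its list mean was -0.76 on the log2 scale relative to the mean over all arrays, where the other 6 arrays lay between -0.02 and 0.32.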
